A study of Homo sapiens with 4 samples.

How the data were processed

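RNA was measured in tissue sections of ovarian cancer with Visium CytAssist, an array of barcoded spots on which gene-specific probe pairs are captured and counted by unique molecular identifiers (UMIs). Each spot covers a small area that can hold several cells of different types. Per the labels' protocols, the human whole-transcriptome probe set, version V2, was used. The labels place all 4 samples in 1 group, surgical minimal residual disease (MRD) after chemotherapy, and the series' design describes 4 cases. The samples were numbered 1 to 4 in the order of their records, and the number carries no meaning beyond a name. P-values of the gene tests measure how the difference between spot classes varied across these 4 cases, with a spread partly pooled across genes. Antibody tests rest on 3 of the cases.

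The deposited matrices hold raw UMI counts per gene and spot, 1 matrix per sample. They were made with Space Ranger against GRCh38. Its version is 2.0.0 per the submitters' processing notes and 2.1.0 per the file headers. The sources used here do not state whether the deposited barcodes were limited to spots over tissue, and no image or spot position was used. The probe assay counts only RNA that its probes bind, so a gene without a row has no value here. The matrices have 18085 gene rows, and 26 genes of the lists fixed for this work have none, KRT18 and most HLA genes among them. The matrices of samples 2, 3 and 4 also hold 35 antibody features, 31 against named targets and 4 isotype controls. These antibody values are deposited as whole-number scores, not counts: the 4 isotype controls of a spot sum to a median of 9960 in sample 2, 9953 in sample 3 and 9929 in sample 4. They were therefore used only as scores relative to the isotype controls. The labels do not describe how they were scaled.

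Samples 1 to 4 had 578, 2673, 1243 and 4980 spots and 5845323, 6147193, 1363526 and 116423352 UMIs. Spots under 500 UMIs were left out, which kept 98.3%, 46.3%, 40.4% and 100.0% of the spots. Samples were compared in pairs before use. Pearson's r of log2 CPM across genes lay between 0.807 and 0.894, and chi-square per gene between 33.0 and 396.9, so no sample was a second copy of another.

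With 1 group, the replicated comparisons are between spot classes within the samples. A spot's score for a list was the mean over its markers of log2(1 + UMIs per 10000). The epithelial minus stromal score (7 and 8 measured markers, among them EPCAM, KRT7, KRT8, COL1A1, DCN and LUM) ordered the spots of each sample, and its top and bottom 25% were the epithelial-marker-high and stromal-marker-high classes. In the 50% of spots with the lower epithelial minus stromal score, the top and bottom 25% of the score of 8 leukocyte markers, among them PTPRC and CD2, made the next pair of classes. In the other 50%, the top and bottom 25% of the score of 8 hypoxia markers, among them CA9 and VEGFA, made the last pair. A class is a range of a score, not a cell type. In samples 1 to 4, 54, 147, 51 and 323 spots lay within 0.1 of a limit of the first pair, 188, 702, 215 and 1538 of the leukocyte pair, and 203, 519, 209 and 2798 of the hypoxia pair. Markers that formed a class stayed in the library sizes and were left out of the tests of that comparison.

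UMIs were summed per sample and class, which gave 8 libraries per comparison, and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with the sample as a block, TMM normalization and the filterByExpr filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. The block pairs 2 sums from the same section, so the pairing comes from the design. CPM values in the gene tests, and the log2 ratios of summed lists between classes unless plain CPM is named, are scaled by TMM library sizes. Levels per sample and per class are plain CPM over all gene UMIs.

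Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Lists needed 3 tested members. Camera with a correlation estimated per list and fry were run beside it. Of 41 lists, 4 formed classes, 16 hold cell type markers and 21 hold genes of programmes. Some genes stand in more than 1 list, such as MMP9, KIT, THY1, CDH6, VTCN1 and CD276. The MHC class II list has 2 measured members, too few to test as a list. Antibody scores were used as deposited, without further scaling, and spots with an isotype sum under 9000 were left out. The scores were log2 transformed after adding 1, averaged per sample and class, and tested with limma and a sample block in 3 samples. The antibody comparison was chosen after seeing the files.

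Regions were found per sample by Leiden clustering of log-normalized counts (2000 variable genes, 30 principal components, 15 neighbours, resolution 0.5, igraph 0.11.9, scikit-learn 1.9.0), and regions of at least 10 spots are described by their number and leading genes. No deconvolution was run, and no cell-type share is given. List scores were correlated across spots after every spot was thinned to 500 UMIs. Spots are not replicates, so r is given per sample. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used, with matplotlib 3.10.9 for plots.

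The genes named in the text follow a rule fixed before the data were examined. They are the 8 called genes with the largest change in each direction, changed the same way in all 4 samples and with at least 50 CPM on average in the higher class. To these come up to 3 called members per list, or the 2 members with the highest mean CPM where none was called, and every tested member of the surface drug target and immune checkpoint lists. Some genes that the rule takes are not reported here. For levels per sample, the rule takes the 2 members of a list with the highest mean CPM. The lists, the classes, the tests and 85 alternatives were fixed before the data were examined as well, and 3 alternatives were added later. The alternatives changed the class size, the UMI minimum, the class score, the depth of spots, the classing markers, the normalization, the low count filter, the tool (the Wald test of DESeq2 1.42.0), the block, the fold minimum, the set test, the resolution and the samples used. With thinned spots the classes were formed anew from the thinned UMIs.

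The gene tests were tried on simulated counts drawn from the real means and library sizes. With 8-fold changes, the first comparison recovered 92.3% of changed genes (15471 genes in the step), the leukocyte comparison 100% (10761 genes) and the hypoxia comparison 77.4% (14585 genes). With 4-fold changes these shares were 61.9%, 93.8% and 42.9%. With 2-fold changes they were 0%, 35.6% and 0%. Between 2 and 18 unchanged genes were called in each. Smaller changes were thus mostly below what 4 samples at this depth can show in the first and last comparisons. For the list test, 20 simulations each used independent normal noise in place of counts. There all shifted lists and at most 1.2% of unshifted lists were called. Genes in that noise were uncorrelated, so the share does not give the rate of false calls among lists whose members vary together. Random classes within the samples, drawn 5 times per comparison, called at most 1 gene. For antibodies, a simulated shift of 1.5 on the log2 scale with the residual SD of the data was recovered for 69.2%, 89.0% and 77.8% of 8 shifted targets, and at most 2% of the others were called. That simulation was redone with the residual SD of the data after the antibody results had been seen.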

Results

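Whole-transcriptome spot profiles were collected from tumour tissue of 4 cases of ovarian cancer that were positive for minimal residual disease (MRD), tumour that remains after frontline therapy. The labels put all 4 samples in 1 group, surgical MRD, with chemotherapy as the treatment, and give no control or untreated sample. The comparisons therefore lie within the samples, between classes of spots. Each case counted once, so n is the number of samples, which are named by their replicate number in the group (samples 1 to 4).

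Depth differed widely between the samples. Sample 4 had 4980 spots with a median of 23087 UMIs, and sample 1 had 578 spots with a median of 3312. Samples 2 and 3 had 2673 and 1243 spots with medians of 455 and 317 UMIs, so 46.3% and 40.4% of their spots reached 500 UMIs. Values from samples 2 and 3 rest on fewer molecules than those from sample 4, which had 116423352 of all UMIs against 5845323, 6147193 and 1363526 in samples 1 to 3.

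**Figure D1:**
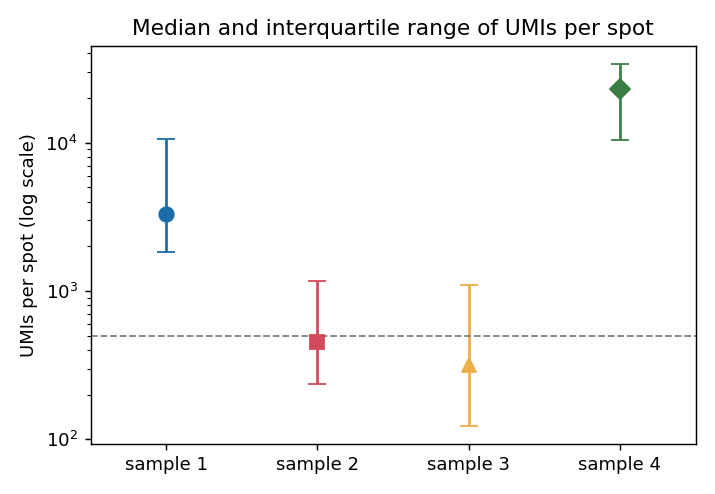
Median UMIs per spot (points, log axis) and interquartile range (bars) in the 4 surgical MRD samples. The dashed line marks the minimum of 500 UMIs per spot, above which the medians of samples 1 and 4 lie (3312 and 23087) and below which those of samples 2 and 3 lie (455 and 317).

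The samples differed in the cell type markers they held, given here as plain CPM over all gene UMIs of a sample. Epithelial check genes (PAX8, WFDC2, KRT19, CD24 and others, 10 genes) summed to 4196, 1553, 625 and 5212 CPM in samples 1 to 4, a mean of 2896 (SD 2161, n = 4). WFDC2, the gene of the serum marker HE4, had 1576, 48.3, 177 and 861 CPM. Plasma cell genes summed to 2999, 20972, 48701 and 11257 CPM, and most of this came from the immunoglobulin genes IGKC (2022, 14846, 28908 and 7979 CPM) and IGHG1 (545, 5493, 17172 and 2868 CPM). B cell genes reached 1399 CPM in sample 3 and between 60.6 and 103 CPM in the others. Fibroblast check genes summed to 10812, 17802, 6368 and 5751 CPM, and smooth muscle and pericyte genes to 1277, 2299, 2723 and 4987 CPM. Endothelial genes had a mean of 1020 CPM (SD 836, n = 4), macrophage genes 1685 (SD 811), T cell genes 475 (SD 219), proliferation genes 703 (SD 364) and MHC class II genes, here CD74 and CIITA, 2812 (SD 1869). With each spot weighted equally, the mean was 1875 CPM for epithelial check, 1577 for endothelial and 5128 for smooth muscle and pericyte genes, against 2821 for the last over all UMIs. Equal weights also gave 2115 and 890 CPM of epithelial check genes in samples 1 and 2, 212 and 794 of B cell genes in samples 1 and 3, and 17158 of plasma cell and 11675 of smooth muscle and pericyte genes in sample 4. The samples have no groups to compare, so these levels were not tested.

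Clustering gave 5, 6, 5 and 14 regions of spots in samples 1 to 4. Region 1 of sample 4 (996 spots) was led by SST, ADGRF1 and SCGB2A1, and region 3 (11.5%) by the matrix genes EPYC, COL11A1 and COL10A1. Region 9 of sample 4 (5.1%) was led by CCL19, IL7R and CCR7, genes of lymphoid tissue. Region 2 of sample 2 (21.1%) and region 5 of sample 4 (9.7%) both had CXCL9, PLA2G2D and MMP9 among their leading genes. In sample 3, region 4 (11.6%, 58 spots) was led by FDCSP, LTF, CR2, PAX5 and MS4A1, genes of B cell follicles. In sample 2, region 5 (10.9%, 135 spots) was led by ACTA1, CKM and MYL2, genes of striated muscle. These last 2 regions had the highest mean epithelial minus stromal score of their samples (-1.81 in sample 3 and -1.29 in sample 2).

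The first comparison set epithelial-marker-high against stromal-marker-high spots of the same sections. The epithelial genes KRT19 and PAX8, the cell cycle genes TOP2A and CDK1, the cholesterol synthesis gene SQLE and the drug target genes MSLN and ERBB2 were higher in the epithelial-marker-high spots. The fibroblast gene PDGFRA, the endothelial gene CLDN5, the macrophage gene CD163, the immunoglobulin gene IGHA1 and the immediate early gene FOSB were lower. Of 16192 genes tested, 114 were higher and 253 lower in edgeR's quasi-likelihood test. PAX8, a transcription factor of Müllerian epithelium, averaged 535 CPM (SD 543, n = 4) against 80.5 CPM (SD 53.6), a log2 fold change of 2.44 ± 0.42 (SE; adjusted p 0.0216; higher in 4 of 4 samples). KRT19, a keratin of simple epithelium, rose by 2.54 ± 0.44 and PI3, the protease inhibitor elafin, by 3.10 ± 0.42 on the log2 scale. In sample 3, PAX8 had only 17 against 3 UMIs and KRT19 4 against 1. PDGFRA, a growth factor receptor of fibroblasts, fell, with a log2 fold change of -4.095 ± 0.51 (adjusted p 0.0178; lower in 4 of 4 samples), as did PLA2G2A (-4.80 ± 0.835) and the matrix protein gene MGP (-3.97 ± 0.71).

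Of the 10 epithelial check genes, 3 rose (KRT19, PAX8 and CD24), 8 when adjusted over the list alone. This list was called higher, with an adjusted p of 0.372 with an estimated correlation. Log2 ratios of lists per sample are from summed TMM-scaled CPM unless plain CPM is named. For this list they were 2.485, 1.46, 0.094 and 2.90 in samples 1 to 4, and 2.53, 1.38, 0.333 and 2.66 in plain CPM. The median spot had 15.9 against 9.81, 5.47 against 2.44, 1.42 against 0 and 66.4 against 7.62 UMIs per 10000 of these genes in samples 1 to 4. The median spot of sample 3 had 0 UMIs of the epithelial classing markers in both classes, so its epithelial-marker-high class was set by low stromal markers (a median of 38.1 against 312.5 UMIs per 10000). Of 12 proliferation genes 5 rose, 10 when adjusted over the list alone, among them TOP2A (log2 fold change 1.73 ± 0.32), CCNB1 (1.80 ± 0.36) and the cell cycle kinase CDK1 (1.66 ± 0.34). The proliferation list was higher by 1.495, 1.28, 1.44 and 1.80 in samples 1 to 4, with an adjusted p of 0.259 with an estimated correlation and 0.0427 by fry. In sample 3, 91 of the 125 epithelial-marker-high spots lay outside region 4, and without that region the proliferation UMIs were 39 against 37. Beside it, the B cell list, which was not called, had a log2 ratio of 2.14 in sample 3 against -0.51, -0.38 and -1.75 in samples 1, 2 and 4. Cholesterol synthesis (2 of 12 rose, 5 adjusted over the list alone, with SQLE at 1.775 ± 0.41) was called higher, with an adjusted p of 0.343 with an estimated correlation. Oxidative phosphorylation (0 of 11 rose, 1 adjusted over the list alone) and homologous recombination repair (FANCA rose, 2.04 ± 0.43, 1 of 12 and 1 adjusted over the list alone) were called higher too. Their adjusted p was 0.381 and 0.343 with an estimated correlation.

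Of 18 surface drug targets 4 rose, 11 when adjusted over the list alone. Mesothelin (MSLN) averaged 762 CPM (SD 607, n = 4) against 140 CPM (SD 87.5), a log2 fold change of 2.17 ± 0.49 (adjusted p 0.0455; 4 of 4 samples). ERBB2, the HER2 receptor, rose by 1.70 ± 0.32, LYPD1 by 2.24 ± 0.44 and the phosphate transporter SLC34A2 (NaPi2b) by 2.31 ± 0.47. The folate receptor FOLR1 (2.235 ± 0.56, adjusted p 0.0633), CLDN6 (1.73 ± 0.47, 0.0787) and MUC16 (2.21 ± 0.64, 0.0995) missed the threshold, with higher TMM-scaled CPM in 4 of 4 samples. In plain CPM, FOLR1 and MUC16 each had 8.86 against 8.87 in sample 2. In sample 3 the differences rest on few UMIs: 9 against 3 of MSLN, 5 against 0 of FOLR1 and 5 against 2 of MUC16. The list was called higher (log2 ratios 1.85, 1.25, -0.077 and 2.55 in samples 1 to 4, and 0.162 in plain CPM in sample 3), with an adjusted p of 0.366 with an estimated correlation. Of the immune checkpoint genes, 0 of 14 were called, 2 rose and 2 fell when adjusted over the list alone. That list was called lower by the test, with an adjusted p of 0.383 with an estimated correlation. The log2 ratios of its summed CPM were 0.033, 0.224, -0.109 and 0.921 in samples 1 to 4, and 0.13 in plain CPM in sample 3.

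Among the lists called lower, 6 of 10 fibroblast check genes fell (9 adjusted over the list alone; MMP2 log2 fold change -2.92 ± 0.51, POSTN -2.54 ± 0.45). Of 10 endothelial genes 6 fell (all 10 adjusted over the list alone), with CLDN5 at -2.73 ± 0.52 and CDH5 at -2.41 ± 0.47. Of 10 macrophage genes 8 fell (10 adjusted over the list alone), with the mannose receptor MRC1 at -3.10 ± 0.57, the scavenger receptor CD163 at -2.55 ± 0.51 and the complement gene C1QA at -2.11 ± 0.375. The adjusted p of each of these 3 lists was 0.343 with an estimated correlation. IGHA1 (-2.65 ± 0.40) and JCHAIN (-2.345 ± 0.49) fell among 10 plasma cell genes (5 adjusted over the list alone), and the mast cell genes MS4A2 (-5.60 ± 1.14) and CPA3 (-3.68 ± 0.77) among 6 (4 adjusted over the list alone). Both lists had an adjusted p of 0.343 with an estimated correlation. Immediate early stress genes fell in 4 of 12 cases (6 adjusted over the list alone), among them the transcription factor genes FOSB (-2.485 ± 0.47) and FOS (-2.14 ± 0.50), with an adjusted p of 0.259 with an estimated correlation and 0.0456 by fry. The mesenchymal transition list (LOX and SNAI2 fell, 2 of 12), the TGF-beta response list (TGFB3 fell, 1 of 12), the complement list (1 of 11 fell) and the stem-like list (3 of 11 fell) were also called lower, each with an adjusted p of 0.343 with an estimated correlation. Adjusted over the list alone, 7, 7, 6 and 6 of their members fell, and 1 stem-like gene rose. The stem-like genes that fell were ALDH1A1, ALDH1A3, enzymes of retinoic acid synthesis, and the transcription factor KLF4, all of which stromal cells can also express.

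Lists called lower with no called member were smooth muscle and pericyte, adipocyte, T cell, NK and cytotoxic, dendritic cell, neutrophil, nerve and Schwann, type I interferon response, lymphoid chemokines, MHC class I and matrix remodelling, besides immune checkpoints. Some of these lists had summed log2 ratios above 0 in 1 sample: NK and cytotoxic (0.476), nerve and Schwann (0.445) and type I interferon response (1.03) in sample 1, and T cell (0.767), dendritic cell (0.706), neutrophil (0.317), lymphoid chemokines (0.167) and MHC class I (0.287) in sample 3. In plain CPM, NK and cytotoxic (0.108) and nerve and Schwann (0.096) were above 0 in sample 3 too. The stem-like list had 0.099 in sample 2, and homologous recombination repair, called higher, had -0.066 in sample 1. Over all 28 called lists, the adjusted p with an estimated correlation lay between 0.259 and 0.4965, so 0 lists passed that test, and 2 passed fry. The mesothelial list was not called (adjusted p 0.328 by camera), although its kallikrein member KLK11 rose (2.13 ± 0.49). The lists for B cells (0.192), intestinal epithelium (0.899), hypoxia response (0.7205), interferon gamma chemokines (0.328), unfolded protein response (0.901), glycolysis (0.0948) and drug efflux and detoxification (0.2545) were not called either, each with camera's adjusted p in parentheses. Camera, the median and the mean of the members differed in sign for hypoxia response and unfolded protein response.

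Without sample 1 edgeR called 0 genes (2082 at an unadjusted p under 0.05), while 0 of the 50 called genes that the naming rule took turned direction and 28 of 28 lists were still called in the same direction. Without sample 2 it called 213 genes (38 higher and 175 lower). Without sample 2 the calls of KRT19, CD24, MSLN, ERBB2, LYPD1, TOP2A, CCNB1, CDK1, SQLE, FANCA, KLK11, CDH5, CD163, C1QA, CPA3, FOS, ALDH1A1, ALDH1A3 and KLF4 were lost, without sample 3 those of FANCA, FOS and SQLE, and without sample 4 that of SQLE. It also called 0 genes with classes from the check lists (2564 unadjusted), with classes from regions (833), with library size alone (2632) or with no replicate block (1197), 24 with spots thinned to 500 UMIs (1 higher and 23 lower), 168 with no UMI minimum (23 and 145), 208 with a score from summed markers (111 and 97) and 565 with no low count filter, and DESeq2 called 1210. In the classes from regions, the epithelial class was region 5 in sample 2 and region 4 in sample 3, led by muscle and by B cell follicle genes. Epithelial check genes had less CPM there than in the stromal class (137 against 849 and 297 against 521). Without samples 2 and 3, whose epithelial check list separated least, 190 genes were called (14 higher and 176 lower). That choice was made after seeing the data, in this comparison and in those that follow. Median UMIs per spot were 2269 against 8365, 912 against 1260, 1259 against 1258 and 34867 against 8954 in the epithelial- and stromal-marker-high spots of samples 1 to 4. The classes were formed on epithelial and stromal genes, so a difference in genes that follow those markers is in part given by the classing.

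**Figure D2:**
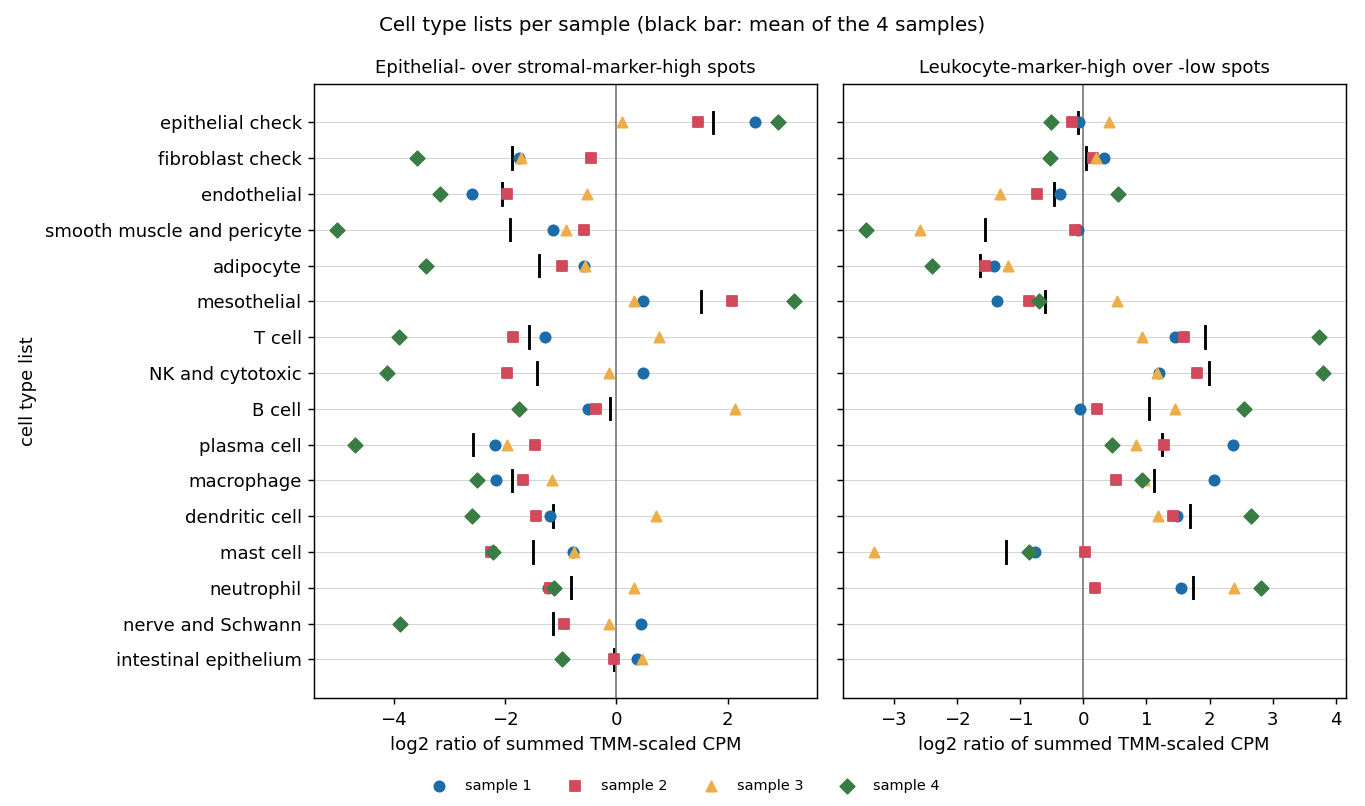
Log2 ratio of the summed TMM-scaled CPM of each cell type list (points, 1 per sample; black bars, mean of the 4 samples) in epithelial- over stromal-marker-high spots (left) and in leukocyte-marker-high over -low spots (right). Fibroblast check, endothelial and macrophage genes lie below 0 in all 4 samples on the left, T cell genes lie above 0 in all 4 on the right, and lists with too few tested members on the right have no points.

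The next comparison set leukocyte-marker-high against leukocyte-marker-low spots in the 50% of spots with the lower epithelial minus stromal score. The T cell gene CD3E, the cytotoxic gene GZMB, the chemokine genes CXCL9 and CXCL10, the interferon-induced gene OAS2, the macrophage gene CD163, the dendritic cell gene IRF8 and the immunoglobulin gene IGHM were higher in the leukocyte-marker-high spots. The fat cell genes PLIN4 and FABP4 and the smooth muscle genes ACTG2 and MYH11 were lower. Of 11406 genes tested, 520 were higher and 229 lower in edgeR's test. The protease gene MMP9 averaged 246 CPM (SD 178, n = 4) against 22.7 CPM (SD 19.97), a log2 fold change of 4.42 ± 0.48 (SE; adjusted p 0.000335; 4 of 4 samples). ZAP70, a kinase of the T cell receptor, rose by 3.61 ± 0.41, and CXCL11 by 3.56 ± 0.37. The lipid droplet gene PLIN4 fell, with a log2 fold change of -4.23 ± 0.51 (adjusted p 0.000417; lower in 4 of 4 samples), as did EPHA7 (-4.02 ± 0.83) and the smooth muscle actin gene ACTG2 (-3.74 ± 0.79).

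All 10 interferon gamma chemokine genes rose, also adjusted over the list alone, among them CXCL9 (3.88 ± 0.43) and CXCL10 (2.745 ± 0.34), which attract T cells. The list was higher by 2.04, 1.79, 1.97 and 1.90 in samples 1 to 4, with an adjusted p of 0.233 with an estimated correlation and 0.0237 by fry. Of 10 T cell genes 9 rose (10 adjusted over the list alone; CD3E 3.27 ± 0.42, IL7R 3.19 ± 0.59), and of 8 NK and cytotoxic genes 6 rose (8 adjusted over the list alone; GZMB 3.64 ± 0.53, GZMA 3.12 ± 0.42). Their adjusted p was 0.508 and 0.306 with an estimated correlation. Of 12 type I interferon response genes 10 rose (11 adjusted over the list alone; OAS2 2.03 ± 0.27, IFI44L 2.05 ± 0.29), with an adjusted p of 0.506 with an estimated correlation. Of 7 tested MHC class I genes 5 rose (5 adjusted over the list alone), among them TAP1, a peptide transporter (1.53 ± 0.25), and NLRC5 (1.55 ± 0.29), with an adjusted p of 0.324 with an estimated correlation. Both measured MHC class II genes rose, CD74 by 1.56 ± 0.36 and the transactivator CIITA by 1.35 ± 0.26.

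Macrophage genes rose in 6 of 10 cases (6 adjusted over the list alone; CD163 1.565 ± 0.32, CD68 1.31 ± 0.27), with an adjusted p of 0.553 with an estimated correlation. Dendritic cell genes rose in 4 of 5 (4 adjusted over the list alone; IRF8 2.07 ± 0.30, LAMP3 2.86 ± 0.59), plasma cell genes in 4 of 10 (6 adjusted over the list alone; IGHM 1.57 ± 0.31), and both had an adjusted p of 0.301 with an estimated correlation. Of 7 lymphoid chemokine genes 5 rose (5 adjusted over the list alone), among them CCL19 (3.625 ± 0.75) and the homing receptor CCR7 (3.785 ± 0.83). Of 6 B cell genes 1 rose (5 adjusted over the list alone), MS4A1 (CD20), by 2.89 ± 0.74 and in 3 of 4 samples. Both lists had an adjusted p of 0.577 with an estimated correlation. Of 6 neutrophil genes 5 rose (5 adjusted over the list alone), with an adjusted p of 0.508 with an estimated correlation. Of those named, MMP9, FPR1 (1.87 ± 0.45) and CSF3R (1.76 ± 0.36) are also genes of macrophages.

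Immune checkpoint genes rose in 5 of 13 cases (6 rose and 1 fell adjusted over the list alone), with an adjusted p of 0.301 with an estimated correlation. They were TIGIT (2.365 ± 0.405), LGALS9 (1.64 ± 0.25), HAVCR2 (TIM-3, 1.30 ± 0.26), CD274 (PD-L1, 1.84 ± 0.49, adjusted p 0.0335) and LAG3 (1.155 ± 0.32, higher in 3 of 4 samples). PDCD1 (PD-1) had a log2 fold change of 2.30 ± 0.80 and was not called (adjusted p 0.103). Among 10 smooth muscle and pericyte genes 5 fell (7 adjusted over the list alone; MYH11 -3.27 ± 0.83), and 2 of 6 adipocyte genes fell (2 adjusted over the list alone; PLIN4 and FABP4). Their adjusted p was 0.553 and 0.301 with an estimated correlation. The endothelial list was called lower with 0 of 10 members called, and its adjusted p was 0.6075 with an estimated correlation. Its log2 ratios were -0.362, -0.736, -1.32 and 0.555 in samples 1 to 4. Of the lists called higher, B cell had -0.047 in sample 1 and lymphoid chemokines had -0.016 in sample 2. Smooth muscle and pericyte genes had log2 ratios of -0.09, -0.126, -2.58 and -3.44 in samples 1 to 4. With the estimated correlation 0 of 34 lists were called, and fry called 6, of which 5 were higher. The other 19 lists were not called by camera, among them proliferation (adjusted p 0.8235), complement (0.657), fibroblast check (0.537), epithelial check (0.643) and surface drug targets (0.492). For hypoxia response and homologous recombination repair, both uncalled, camera, the median and the mean differed in sign. Within lists that were not called, the glycolytic regulator PFKFB3 (1.68 ± 0.28), the adhesion molecule CD44 (1.32 ± 0.25), TGFB1 (1.16 ± 0.32), PLAUR and TIMP1 rose, and CALB2 fell.

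Without sample 4, 453 genes were called, and the log2 fold changes of CCL19 (1.46), CD3E (1.97), IL7R (1.59), TIGIT (1.305) and NLRC5 (1.01) were smaller. Without sample 4, GZMB (1.62), MS4A1 (0.767), CSF3R (1.27), HAVCR2 (0.957), CIITA (0.997), LAG3 (0.836), PLAUR, TGFB1, TIMP1 and CALB2 were no longer called. Of the 57 called genes that the naming rule took, 47 were tested in that fit. Without sample 3 the calls of ACTG2, MYH11, FABP4, MS4A1, TGFB1, CD274, PLAUR, TIMP1 and CALB2 were lost, without sample 1 those of C1QA, CD74, LAG3, TGFB1 and TIMP1, and without sample 2 those of CD74, LAG3 and TIMP1. The C1QA call (1.29 ± 0.29) was also lost without sample 3. With no replicate block 118 genes were called (115 higher and 3 lower), with no low count filter 1156, and with spots thinned to 500 UMIs 34 of 1466 tested. Without samples 2 and 3, 1055 genes were called. FABP4 turned with classes from the T cell and macrophage lists (log2 fold change 0.159, adjusted p 0.877). Median UMIs per spot were 12963 against 2404, 3584 against 761, 2531 against 972 and 13730 against 8502 in the leukocyte-marker-high and -low spots of samples 1 to 4. Because these classes were formed on leukocyte genes, a difference in genes that follow those markers is in part given by the classing.

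Antibody scores of samples 2, 3 and 4 were compared between the same classes, a comparison chosen after seeing the files. In leukocyte-marker-high spots, 9 of 31 targets were higher in limma's test and 0 lower, and 21 of 31 were higher in 3 of 3 samples and 0 lower in all. The 21 include the epithelial targets KRT5 (0.437 ± 0.19) and EPCAM (0.294 ± 0.205), neither of them called. The count of 21 is therefore not particular to leukocyte targets. HLA-DRA, a class II molecule with no RNA row here, was higher by 1.83 ± 0.22 on the log2 scale (SE, n = 3; adjusted p 0.00136; 3 of 3 samples), and the co-receptor CD8A of cytotoxic T cells by 2.20 ± 0.275. CD3E (1.65 ± 0.24), CD68 (1.46 ± 0.23), PD-L1 (CD274, 1.39 ± 0.21), ITGAX (1.40 ± 0.25), CXCR5 (0.921 ± 0.24) and both PTPRC antibodies (0.831 ± 0.23 and 0.962 ± 0.28) were higher as well. PTPRC RNA was among the markers that formed these classes. Between epithelial- and stromal-marker-high spots, limma called 0 targets (5 at an unadjusted p under 0.05), and 18 were lower in 3 of 3 samples. EPCAM scores differed there by 0.109, -0.103 and 2.90 in samples 2, 3 and 4. Scores of PCNA, a member of the proliferation list, differed by -1.193, -1.539 and 1.294. Between hypoxia-marker-high and -low spots limma called 0 targets (1 unadjusted).

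**Figure D3:**
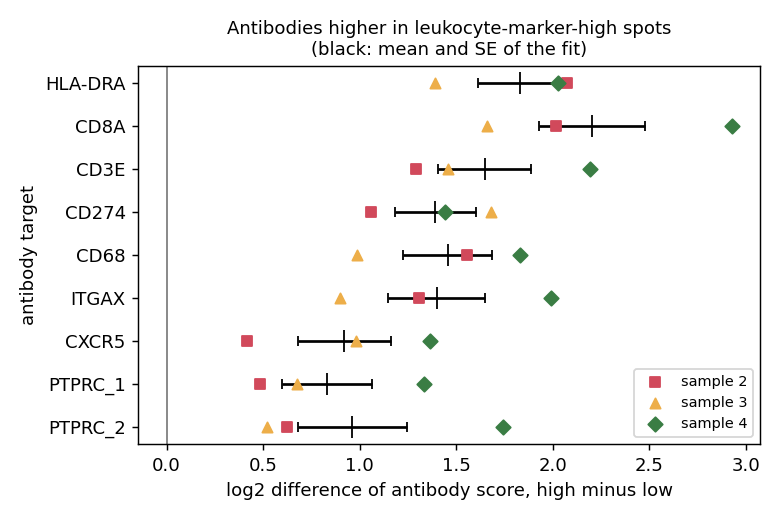
Difference in log2 antibody score between leukocyte-marker-high and -low spots (horizontal axis) for the 9 targets called higher (vertical axis), with 1 point per sample and the mean ± SE of the fit in black. All points of samples 2, 3 and 4 lie above 0, and the means run from 0.831 (PTPRC_1) to 2.20 (CD8A).

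The last comparison set hypoxia-marker-high against hypoxia-marker-low spots in the 50% of spots with the higher epithelial minus stromal score. TRDN, AMPD1, APOBEC2, MYOM3, KLHL41, LDB3, SMPX and SCARA5 were among the genes lower in the hypoxia-marker-high spots, and PLEKHG4B was the 1 gene called higher. Of 16293 genes tested, 1 was higher and 35 were lower in edgeR's test. The median log2 fold change of all genes was 0.195 with TMM, -0.077 with DESeq2's size factors and -0.173 with library size alone, so changes are given relative to the median of 0.195. TRDN, which encodes triadin of the muscle calcium release complex, averaged 3.45 CPM (SD 4.61, n = 4) against 154 CPM (SD 285). Its log2 fold change was -4.87 ± 0.79, or -5.07 relative to the median (adjusted p 4.059e-06; lower in 4 of 4 samples). That p-value rests on a spread pooled across genes, while the SD of TRDN in the hypoxia-marker-low spots exceeded its mean. AMPD1 (-3.885 relative to the median), APOBEC2 (-3.81), MYOM3 (-3.81), KLHL41 (-3.71), LDB3 (-3.69) and SMPX (-3.07), all known from striated muscle, and SCARA5 (-3.16), a scavenger receptor gene of fibroblasts, were lower too. PLEKHG4B was 2.09 higher relative to the median (log2 fold change 2.28 ± 0.57, adjusted p 0.0369).

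The 35 lower genes had a median of 373 plain CPM in the hypoxia-marker-low spots of sample 2, against 36.1, 15.9 and 0.36 CPM in those of samples 1, 3 and 4. Without sample 2 edgeR called 0 genes (324 at an unadjusted p under 0.05), and the log2 fold changes were -2.14 for TRDN, -1.78 for AMPD1, -1.705 for APOBEC2, -1.79 for MYOM3, -1.95 for KLHL41, -2.04 for LDB3, -1.29 for SCARA5 and 1.49 for PLEKHG4B. Fold changes without 1 sample are as fitted, and the median of all genes was 0.071 without sample 2 and 0.1 without sample 4. The call of PLEKHG4B was also lost without sample 1, 3 or 4, that of LDB3 without sample 3 and that of SMPX without sample 1, and the count was 66, 57 and 62 genes without samples 1, 3 and 4. Without sample 4 the log2 fold changes of KLHL41 (-5.95), LDB3 (-5.49) and SMPX (-4.46) were larger, and TRDN, AMPD1, APOBEC2 and MYOM3 were not tested. Hypoxia response genes outside the classing markers were not called as a list (camera's adjusted p 0.154), with log2 ratios, not set relative to the median, of 0.693, 0.684, -0.03 and 0.81 in samples 1 to 4. In plain CPM these were -0.011, 0.124, -0.437 and 0.75. Lists called higher were epithelial check (list median 1.56 relative to the median of all genes, 0 of 10 called, 7 adjusted over the list alone), proliferation (0.713, 0 of 12, 1), surface drug targets (0.855, 0 of 18, 4), glycolysis (0.58, 0 of 9, 1), unfolded protein response (0.445, 0 of 11, 0) and type I interferon response (0.607, 0 of 12, 0). Lists called lower were endothelial (-1.43, 0 of 10 called, 4 adjusted over the list alone), smooth muscle and pericyte (-1.09, 0 of 10, 4), adipocyte (-1.87, 0 of 10, 3), intestinal epithelium (-1.87, 0 of 8, 0), nerve and Schwann (-1.09, 0 of 8, 0) and lymphoid chemokines (-0.866, 0 of 8, 0). Over these 12 lists the adjusted p with an estimated correlation lay between 0.764 and 0.786, and 0 of 36 lists passed that test or fry. The log2 ratios of summed lymphoid chemokines were 0.611, 0.004, 0.585 and -0.468 in samples 1 to 4, and -0.093, -0.556, 0.177 and -0.527 in plain CPM. Smooth muscle and pericyte genes had 1.44 in sample 1 (0.737 in plain CPM), and proliferation genes -0.144 in sample 4 (-0.203). Type I interferon response in sample 2 (0.329) and surface drug targets in sample 3 (0.283) had -0.232 and -0.124 in plain CPM. In the mesothelial, macrophage, immune checkpoint and drug efflux lists, none of them called, camera, the median and the mean of the members differed in sign.

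Median UMIs per spot were 22346 against 1821, 16317 against 661, 3660 against 853 and 33965 against 31467 in the hypoxia-marker-high and -low spots of samples 1 to 4. Epithelial check genes had 7576 against 1155.5, 2142.5 against 599, 851 against 461 and 6892 against 5990 plain CPM there. The lists called between these classes cannot be told apart from this difference in epithelial markers. In sample 4, where it was smallest, log2 ratios were 0.463 for glycolysis, 0.348 for type I interferon response and 0.229 for surface drug targets. They were 0.095 for unfolded protein response and -0.144 for proliferation genes. EdgeR called 21 genes with spots thinned to 500 UMIs (1781 tested, 0 shared with the 36), 121 with library size alone, 97 with DESeq2's size factors, 0 with no replicate block (274 unadjusted) and 1 without samples 2 and 3, and DESeq2 called 21.

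List scores were correlated across spots thinned to 500 UMIs in each sample, for 36 pairs of 9 lists. In 11 pairs r had the same sign in 4 of 4 samples, 7 positive and 4 negative, where chance gives 12.5% of pairs. Macrophage and MHC class II scores had a mean r of 0.238 (SD 0.035, n = 4), and T cell and plasma cell scores a mean r of 0.158 (SD 0.034). Epithelial check and endothelial scores had a mean r of -0.138 (SD 0.083), and macrophage and proliferation scores of -0.063 (SD 0.057). The sign of the last pair was mixed in unthinned spots, with r of 0.024, 0.017, 0.038 and -0.519 in samples 1 to 4. With Spearman's rho it was mixed too (0.012 in sample 1). An exact sign-flip test over 4 values cannot reach 0.05, so no pair was called.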

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

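Among 147 sets of 4 sample values, 13 held a sample whose gap to the nearest other was a large share of the range of all 4, where chance gives about 7.3, so part of these are expected by chance. No explanation was tested for them except where the last part of this section takes one up.

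In plain CPM, the leukocyte classing markers summed to 2329.29 in sample 3, against 740.53, 442.7 and 483.62 in samples 1, 2 and 4. The B cell list summed to 1399.36 in sample 3, against 93.93, 103.1 and 60.56 in the others. The hypoxia response list reached 761.89 in sample 4, against 375.22, 394.54 and 419.08 in samples 1 to 3. TGF-beta response genes summed to 2350.58 in sample 2, against 1344.51, 1299.46 and 1257.02 in samples 1, 3 and 4.

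The log2 ratios below are from summed TMM-scaled CPM. Between epithelial- and stromal-marker-high spots, the ratio of the smooth muscle and pericyte list was -5.017 in sample 4, against -1.139, -0.588 and -0.899 in samples 1 to 3. For the adipocyte list it was -3.417 in sample 4, against -0.576, -0.98 and -0.56. The neutrophil list was higher by 0.317 in sample 3, against -1.234, -1.195 and -1.125 in samples 1, 2 and 4. Cholesterol synthesis had a ratio of 0.322 in sample 3, against 1.753, 1.555 and 1.525. Homologous recombination repair had a ratio of -0.066 in sample 1, against 0.772, 0.818 and 0.823 in samples 2 to 4.

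Between leukocyte-marker-high and -low spots, oxidative phosphorylation had a log2 ratio of -0.498 in sample 4, against 0.087, 0.069 and 0.14 in samples 1 to 3. Cholesterol synthesis had one of 1.229 in sample 3, against -0.23, -0.042 and -0.063 in the others. Between hypoxia-marker-high and -low spots, the nerve and Schwann list had a ratio of -3.341 in sample 1, against -0.487, -0.277 and -0.237 in samples 2 to 4. The hypoxia response list had one of -0.03 in sample 3, against 0.693, 0.684 and 0.81 in samples 1, 2 and 4, and in plain CPM -0.437 against -0.011, 0.124 and 0.75.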

How the results depend on the processing

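The settings without replicates 2 and 3 were chosen after seeing the data, and all others before. For changes not explained here, the cause was not tested.

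Between epithelial- and stromal-marker-high spots, the 367 genes became 168 with no UMI minimum, 208 with a score from summed markers, 24 with thinned spots (4427 genes tested), 565 with no low count filter, 1210 with DESeq2 and 190 without replicates 2 and 3. EdgeR called 0 with classes from other markers, from Leiden clusters or with library size alone (2564, 833 and 2632 at an unadjusted p under 0.05). The 28 lists became 0 with an estimated correlation, 2 with fry and 17 with thinned spots, where 23 of the 28 could be tested. Without 1 replicate the genes ranged from 0 to 548 and the lists from 22 to 29.

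Between leukocyte-marker-high and -low spots, the 749 genes became 34 with thinned spots (1466 tested) and 1156 with no low count filter. The 15 lists became 0 with an estimated correlation, 6 with fry and 6 with thinned spots, where 9 of the 15 could be tested. FABP4 turned to a log2 fold change of 0.159 with classes from other markers. Without 1 replicate the genes ranged from 453 to 838 and the lists from 15 to 20.

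Between hypoxia-marker-high and -low spots, the 36 genes became 64 with wider classes, 55 with classes from other markers, 97 with DESeq2's size factors, 121 with library size alone, 59 with no low count filter, 21 with thinned spots (1781 tested), 21 with DESeq2 and 1 without replicates 2 and 3. The 12 lists became 0 with an estimated correlation, 0 with fry and 0 with thinned spots, where 7 of the 12 could be tested. Without 1 replicate the genes ranged from 0 to 66 and the lists from 7 to 14.

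With no replicate block, 0, 118 and 0 genes were called in the 3 comparisons, with 1197, 989 and 274 at an unadjusted p under 0.05. The block takes out the differences between sections.

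With each spot weighted equally, mean CPM was 5127.58 for smooth muscle and pericyte, 392.7 for adipocyte, 141.05 for nerve and Schwann and 62.84 for intestinal epithelium genes, and the other list levels moved by less than 1 SD. At resolution 1.0 sample 1 had 8 regions. The 11 pairs of lists with r of 1 sign ranged from 12 to 19 without 1 replicate, a count that cannot fall, since a pair of 1 sign in 4 samples keeps it in 3. Of the mean correlations, 24 of 252 moved by over 1 SD, 23 of them in unthinned spots. Other gene counts stayed within 1.5 times. Depth limits which genes can be tested: 16192, 11406 and 16293 were at full depth in the 3 comparisons, against the 4427, 1466 and 1781 in thinned spots.

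Of the 8 ways to exchange the classes within samples, 1 (the real one) gave as many genes in each comparison. The real and highest other counts were 367 and 0, 749 and 0, and 36 and 29, and 8 splits are too few for a share under 0.05.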

Other observations

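The comparison of antibody scores with RNA and the tests below were chosen after the results were seen, except the tests of muscle in sample 2 and of calls in thinned spots for the genes lower in hypoxia-marker-high spots. The samples form 1 group, so the design names no biological explanation for the patterns below, and none from the design was tested. The EPCAM test replaced one on the spot classes of sample 2 (a difference of 0.109), and the bounds of the depth tests in proliferation genes and in sample 2 were reset after their first results. Ranges in parentheses for thinned spots and antibodies are 95% intervals over resampled spots, which are not replicates.

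Antibody scores and RNA of the same gene were correlated across the spots of samples 2, 3 and 4, and spots are not replicates. For 23 of 30 antibodies r was above 0 in all 3 samples, with a median mean r of 0.202. Smooth muscle actin (ACTA2) had r of 0.528, 0.478 and 0.864, the integrin ITGAX 0.482, 0.336 and 0.629, and vimentin (VIM) 0.357, 0.17 and 0.862. The B cell factor PAX5 had r of 0.456 in sample 3, against -0.017 and 0.086 in samples 2 and 4, and the complement receptor CR2 had 0.425, against -0.011 and 0.009. For CD4 r was 0.1, 0.106 and 0.106. RNA of sample 4 held 81262 EPCAM UMIs, against 67 and 34 in samples 2 and 3, and r for EPCAM was 0.9, 0.027 and 0.277 there.

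In sample 2, EPCAM had 67 UMIs beside 1882 of PAX8 and 3338 of MSLN. In its epithelial-marker-high spots EPCAM had 12.6 CPM, KRT8 666, PAX8 437 and WFDC2 37.8, against 3.8, 196, 112 and 101 CPM in the stromal-marker-high spots. CDH1 (1.87 CPM), CLDN4 (6.53), FOLR1 and MUC16 (8.86 each) were also low in the epithelial-marker-high spots of sample 2. They had 223, 444, 585 and 1158 CPM in those of sample 4. A failed EPCAM probe would not account for these genes, but for EPCAM itself a probe failure in sample 2 alone stays open. The EPCAM antibody score of sample 2 was 0.341 higher (0.225 to 0.47) in the 72 spots with the highest epithelial check share than in the lower 50% of spots of at least 1000 UMIs, against 2.379 in sample 4. But those 72 spots held a median of only 26.8 UMIs per 10000 of the check genes, against 74.7 in sample 4. Mesothelial cells could be a source, but 4 of 10 mesothelial markers were at least 2 times higher in the epithelial-marker-high spots of sample 2, between the bounds set. In samples 1, 3 and 4, 2, 2 and 4 were. Levels differed more than these counts: LRRN4 and UPK3B had 565 and 608 CPM in those spots of sample 2, against 1.3 and 74.2 in sample 4. KLK11 had 54.1 against 730. CALB2, ITLN1, PRG4, HP and CPA4 had 5.13, 7.0, 3.26, 6.06 and 1.4 CPM in those spots of sample 2, so a mesothelial source stays open.

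As summed CPM, proliferation genes were higher in the epithelial-marker-high spots of all 4 samples. The median spot of samples 2 and 3 had 0 UMIs of these genes in both classes. Antibody scores of PCNA, a member of the list, differed by -1.193, -1.539 and 1.294 in samples 2, 3 and 4, and were not called. Across spots, r of these scores with PCNA RNA was 0.212, -0.037 and 0.664. B cells in samples 1, 2 and 4 are argued against, since the highest TMM-scaled log2 ratio of the B cell list there was -0.376. Germinal centre B cells in sample 3 may account for that sample: without region 4, where B cell genes had 3571 CPM, the ratio was 0.599 (-0.046 to 1.243) against 1.671 in all spots, both from plain UMI sums, which leaves it open. With spots thinned to 500 UMIs and classes formed anew from the thinned spots, all 12 members gave log2 ratios from plain UMI sums of 1.066, 0.45, 0.977 and 1.264, and with the classes kept 0.986, 0.377, 0.968 and 1.74, while the 3 members past the filter, on which this test was first run before it was changed to all 12, gave TMM-scaled ratios of 1.285, 0.618, 0.21 and 1.398 in the new classes. Depth as the whole cause is thus argued against in samples 1 and 4, where the lowest bounds were 0.345 and 1.062, and stays open in samples 2 and 3, where they were -0.187 and 0.0.

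The 35 genes lower in hypoxia-marker-high spots include MYH1, MYH2, TRDN and other genes known from striated muscle. Without sample 2, 0 of the 35 were still called lower (26 tested), which met the bound set for muscle tissue in sample 2. But edgeR then called 0 genes of any kind, so this count does not single out muscle. The 35 genes had a median of 373 plain CPM in the hypoxia-marker-low spots of sample 2, and region 5 of that sample was led by genes of striated muscle. Muscle tissue in sample 2 thus stays a candidate source of these genes. In sample 1, background of rarely counted genes in shallow spots is a further candidate, since 96.0% of 4298 other genes under 3 CPM in sample 4 were also lower there. Depth as the whole cause is argued against in sample 2, where the log2 ratio of their summed UMIs was -7.096 at full depth, -5.692 in thinned spots of the same classes (-6.432 to -5.09) and -1.354 in classes formed anew (-2.097 to -0.7), which shared 61 and 58 of 154 spots with the first. For the other samples the count of calls cannot decide, since 0 genes were still called with thinned spots, where 10 were tested and the bound could not be reached. In samples 1, 3 and 4 the log2 ratio was -3.953, -1.433 and -0.373 at full depth. It was -1.771, -0.249 and -0.771 in thinned spots of the same classes. In classes formed anew it was -0.507 (-1.242 to 0.278), 0.715 (-0.001 to 1.471) and -0.765 (-1.448 to -0.097). No bound was set for these ratios, so depth stays open in samples 1, 3 and 4.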
